A study of Mus musculus with 6 samples.

How the data were processed

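The series holds RNA sequencing of small extracellular vesicles (sEV) of mouse embryonic cortical neurons, in 3 libraries labelled OGD/R and 3 labelled control. Groups were taken from these labels. The series text names vesicles of hypoxic (HypEV) and normoxic (NorEV) neurons, and OGD/R was read as the hypoxic group because control is the only other label. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with the Epi mini longRNA-seq kit (Epibiotek). How vesicles were isolated and whether the kit keeps the strand were not given in the sources used here.

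The authors deposited 1 table per library with 53379 Ensembl gene identifiers and their FPKM values (fragments per kilobase of gene, scaled to the fragments of the library). The names of the deposited tables mention HTSeq, a program that counts reads per gene. The aligner, the genome build and the annotation were not given in the sources used here. FPKM divides by the library's total, so a few genes that take many fragments lower the values of all others, and it makes 1 read on a short gene worth many FPKM.

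Depth on genes was read from the values. Of the identifiers, 53274 were found in GENCODE release M21 (GRCm38) and 105 were not. With the length of each gene's longest transcript there, 96.0% of the values above 0 were whole multiples of 1 read, within a tolerance of 0.01 reads. For 51483 genes (96.4%) the reads were whole in all libraries. This gave 1092724, 1413374 and 1494499 fragments for NorEV 1, 2 and 3 and 2141610, 1445674 and 1320916 for HypEV 1, 2 and 3. The reads of all genes summed to 100.4 to 101.1% of these totals, so the totals hold only fragments counted on genes. How many fragments were sequenced but not counted on a gene is not known. One read was worth 0.467 to 0.915 FPKM on a gene of 1 kilobase. Shares of reads are shares of the fragments counted on genes, and have Wilson intervals with a confidence level of 95%. A count of 0 allows up to 3 reads, or 0.000140 to 0.000275% of the reads of a library. Coordinates are those of GRCm38 and GENCODE M21. Overlaps were found with bedtools 2.31.1, and genes over 90% alike over 80% of their length with blastn 2.17.0. Such genes are called near-identical copies here, which overstates some: the highest identity was 91.6% for Gm10801 and 93.0% for n-R5s88. The counting used strand: of 178 genes covered by exons of another gene on the same strand 170 were at 0 in all libraries, against 15 of 273 covered on the opposite strand.

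HypEV was compared with NorEV for 44125 genes with a mean of at least 1 FPKM. Values were taken as log2(FPKM + 1) and tested with limma 3.58.1 (R 4.3.3; eBayes with a trend, two-sided, no covariates), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. A test on counts had been written down as the first choice in case raw counts were given, and this test for FPKM alone. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests a list against no change rather than against other genes. The p-values were adjusted over 33 lists of at least 5 tested genes. Measures of single libraries were compared with exact permutation tests over all 20 assignments. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

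The groups, the tests, the 33 lists, the rule for named genes and the alternatives not said to be added were fixed before the data were examined. The lists cover hypoxia, glycolysis, stress, cell death and inflammation, markers of neurons and of other cells a cortical culture could hold, and mitochondrial, ribosomal, proteasome, vesicle and non-coding RNA genes. Genes were named by a rule. It takes the 10 largest fold changes per direction among genes past the threshold, without predicted or clone names and without overlap of the groups. Where fewer than 5 genes pass in a direction, it takes the 10 smallest p of that direction as values that did not pass. Of each list it takes up to 4 members that passed, or the 2 of smallest p as values, and it adds the 5 most abundant genes. A few genes that the rule takes are not reported here.

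The tests were also run on data simulated from the libraries' own means, with 200 genes changed by known folds among 42019 genes. All genes were given 1 common spread, taken from genes with more reads, and the totals used were chosen after the data were seen. limma called 0, 1, 6 and 29 of 50 genes changed 2-, 4-, 8- and 16-fold, and 20 of 41797 unchanged genes. Reads were drawn on the totals without the Gm23935 family (defined below) and scaled to all fragments, so unchanged genes still shifted in FPKM. limma-voom, added later, called 3, 18, 46 and 50 of 50. In camera a list shifted 2-fold was called and 0 of 32 unshifted lists were. Genes were drawn independently there, so this cannot show how often camera calls lists whose members correlate. In the real data the estimated correlation was 0.167 for mitochondrially encoded mRNAs and 0.251 for cytosolic ribosomal proteins. No library pair was a duplicate: the spread between any 2 libraries was 3.49 to 9.28 times that of counting.

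The alternatives were median scaling, quantile normalization, no filter, a mean of at least 5 FPKM, no trend, a pseudocount of 0.1, a replicate block, each library left out, a threshold on unadjusted p with a log2 fold change above 1, array weights and an estimated correlation. Chosen after seeing the data were limma-voom on the recovered reads, totals without the Gm23935 family (6 near-identical genes), a minimum length of 200 nucleotides, leaving out the 3 libraries with most Gm23935 reads, and an estimated correlation in the 6 settings in which a further list was called. All 6 libraries entered the tests, and no gene was left out by name except where said.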

Results

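Small extracellular vesicles (sEV) are membrane-bound particles that cells release and that carry RNA and protein. RNA of sEV from cultures of mouse embryonic cortical neurons was sequenced in 6 libraries. HypEV, the vesicles of neurons that the series text calls hypoxic, and NorEV, those of control neurons it calls normoxic, had 3 libraries each. The labels give the treatment of HypEV as OGD/R, which they do not spell out. Hypoxia can thus not be told apart here from any other part of that treatment. The comparison asks which RNAs differ between vesicles of the 2 kinds. Each library lists 53379 Ensembl genes in FPKM. The steps between the values gave 1092724 to 1494499 fragments counted on genes per library in NorEV and 1320916 to 2141610 in HypEV. Fragments not counted on a gene are not known. A tested gene held a median of 8 to 16 reads per library. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

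The most abundant entry in the vesicles was Gm23935 (ENSMUSG00000076258), annotated as a microRNA of 57 nucleotides. It lies on chromosome 16 from 11144125 to 11144181 (GRCm38), in an intron of Zc3h7a on the opposite strand. Gm23935 took 4.31% (95% Wilson interval 4.27 to 4.34), 0.554% (0.542 to 0.567) and 0.297% (0.288 to 0.306) of the reads counted on genes in NorEV 1, 2 and 3. In HypEV 1, 2 and 3 it took 49.5% (49.4 to 49.6), 1.95% (1.93 to 1.98) and 24.4% (24.3 to 24.5). These intervals cover counting error only. The group means were 1.72% ± 2.24 and 25.3% ± 23.8 (SD, n = 3), and the difference was not larger than the spread between libraries (exact permutation test, two-sided, p = 0.2). No such test of 3 against 3 can go below 0.1. Gm23935 is over 90% alike to 5 other annotated genes, among them Gm25911, so the split of reads between them is uncertain.

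The other 4 of the 5 most abundant entries were Gm10800, Gm42418, Gm25911 and Mir6236. Gm10800, a predicted protein-coding gene with 10 near-identical copies, had 9292 ± 7805 FPKM in NorEV and 29859 ± 5715 in HypEV. Gm42418, a long non-coding RNA gene known to overlap ribosomal RNA sequence, had 3799 ± 3295 and 8261 ± 8659 FPKM. Gm25911 had 1538 ± 1708 and 8721 ± 6719 FPKM, and Mir6236 had 3396 ± 5222 and 6008 ± 3211 FPKM (SD, n = 3 throughout). None of these entries passed in limma, with a variance trend or without one (standard errors with it of 138 log2 units for Gm23935, 5.204 for Gm10800 and 1.75 to 2.16 for the others). Chosen after seeing the data, limma-voom on the recovered reads with the family of Gm23935 left out of the totals called Gm42418 (log2 fold change 1.90 ± 0.38 SE, adjusted p = 0.00999) and Mir6236 (3 ± 0.54 SE, adjusted p = 0.00221) higher, though their groups overlapped. Gm10800, whose reads were not whole in all libraries, and Gm23935 and Gm25911, of the family left out, did not enter that test. All 3 HypEV libraries of Gm10800 (24527 to 35892 FPKM) were above all 3 of NorEV (2480 to 17808).

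**Figure D1:**
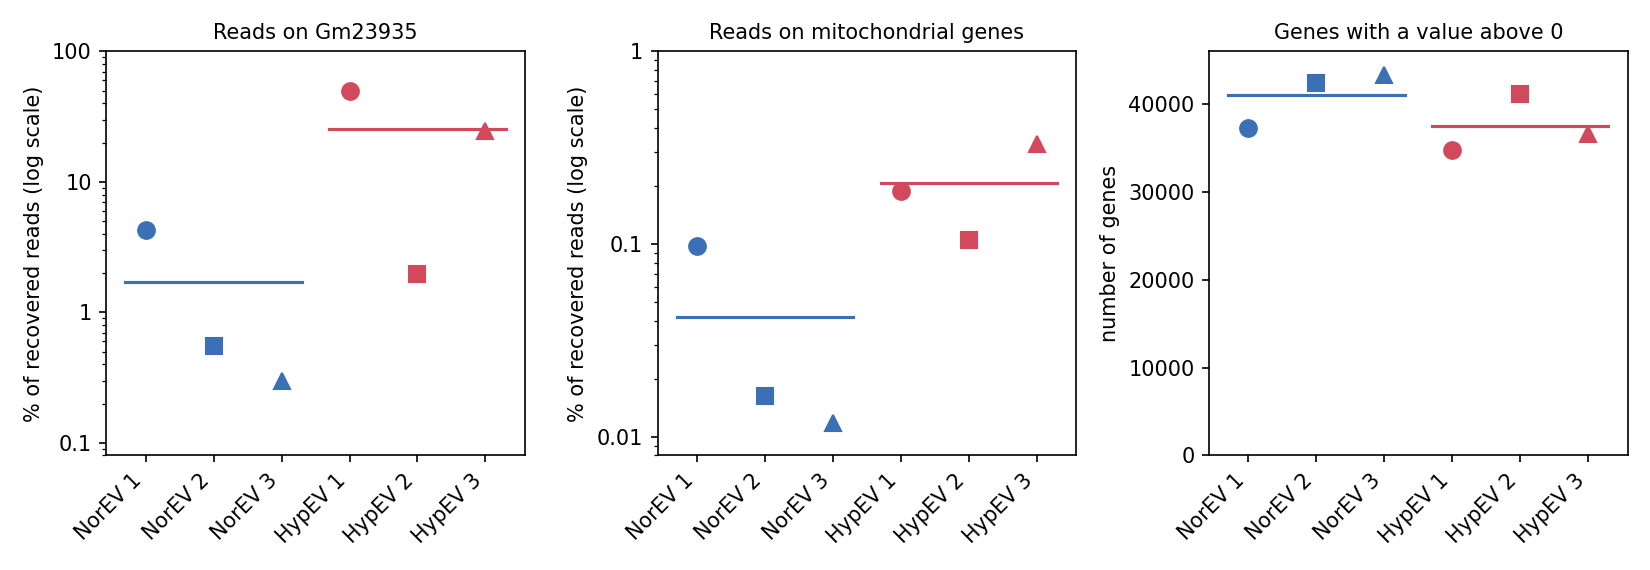
Left and middle, percent of recovered reads on Gm23935 and on genes of the mitochondrial genome in each library (log axes); right, number of genes with a value above 0 (linear axis from 0). Points are libraries, shapes the replicate numbers and lines the group means; Gm23935 took 0.297 to 4.31% in NorEV and 1.95 to 49.5% in HypEV, mitochondrial genes 0.0118 to 0.0973% and 0.105 to 0.330%.

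Genes of many cell types were listed at similar levels in the vesicles. Pan-neuronal markers had a median of 11.8 ± 2.29 FPKM in NorEV and 8.88 ± 2.46 in HypEV (SD over 3 libraries), and glycolytic enzymes, among the most highly expressed genes of most cells, 15.8 ± 1.44 and 14.4 ± 5.30. Astrocyte markers had 11.1 ± 2.22 and 10.4 ± 3.93 FPKM, markers of endothelial, mural and fibroblast cells 9.66 ± 2.92 and 8.33 ± 4.10, and erythroid markers 7.34 ± 3.8 and 5.44 ± 3.13. A set of 72 genes of liver, muscle and other non-neural tissues, chosen after the values were seen, had 8.70 ± 1.41 and 6.59 ± 3.41 FPKM. The ratio of pan-neuronal to non-neural medians was 0.979 to 1.91 in single libraries. Olfactory receptor genes, also chosen after the values were seen, had 2.62 ± 0.218 and 1.77 ± 0.920 FPKM over 1092 genes.

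**Figure D2:**
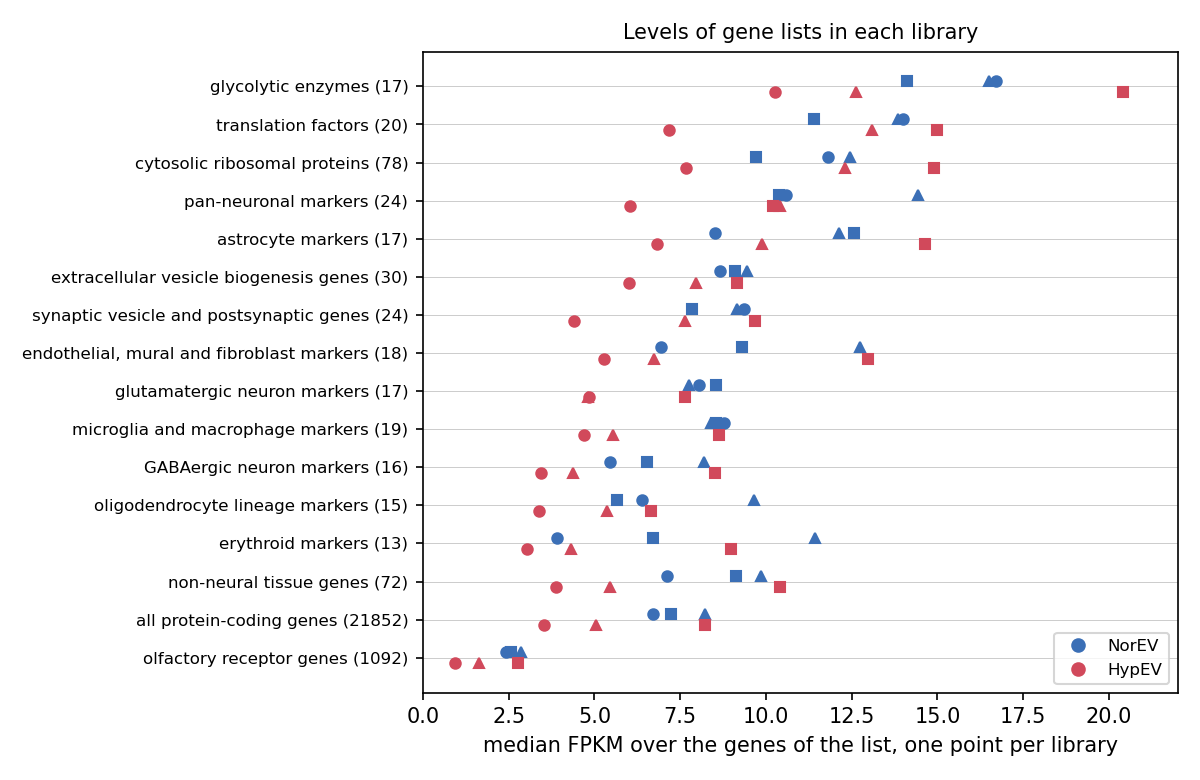
Median FPKM over the genes of each list (linear axis), 1 point per library, with the number of genes in brackets; colours are the groups and shapes the replicate numbers. Pan-neuronal markers lay between 6.04 and 14.4 FPKM, non-neural tissue genes between 3.89 and 10.4, and olfactory receptor genes between 0.936 and 2.86.

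Between HypEV and NorEV, 6 short non-coding RNA genes were lower and 1 was higher of the 44125 genes tested. This count of 7 became 0 under median scaling, no filter, no trend, a pseudocount of 0.1 or a replicate block. It was 5 under quantile normalization, 7 with a mean of at least 5 FPKM, 75 with array weights and 0 to 71 with 1 library left out. Of the runs with 1 library left out, only that without HypEV 2 called any of the 7 genes again. In 12 of 20 simulated sets without a changed gene, described below, at least 7 genes were called. Mir744, a microRNA gene in an intron of Map2k4 (chromosome 11, 65734733 to 65734832), had 36.6, 28.3 and 33.5 FPKM in NorEV and was listed at 0 in all 3 HypEV libraries (adjusted p = 0.0384, limma). Mir3106, in an intron of Csmd1 (chromosome 8, 16168757 to 16168838), had 22.3, 51.8 and 73.4 FPKM in NorEV and was listed at 0 in HypEV (adjusted p = 0.0449). Mir7233 (chromosome 6, 127788084 to 127788143), outside any other gene, was listed at 0 in NorEV and had 38.9, 34.6 and 25.2 FPKM in HypEV (adjusted p = 0.0384). Mitochondrially encoded mRNAs stood higher as a group (adjusted p = 2.13e-08, camera), but did not pass with an estimated correlation (adjusted p = 0.358). Of 713 tested genes of the 33 fixed lists 0 passed by themselves. None of the 20356 tested protein-coding genes passed.

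The remaining 4 entries past the threshold fell outside the rule for named genes and are named after their values were seen. They were the small nucleolar RNA genes Gm24599 (54.9, 84.9 and 40.1 FPKM in NorEV) and Gm25496 (38.1, 41.3 and 27.9), the small nuclear RNA gene Gm23940 (34.9, 101.1 and 38.2) and the microRNA gene Gm27529 (22.9, 53.1 and 50.2). All 4 were listed at 0 in HypEV, with an adjusted p of 0.0384. Gm24599 has 17 near-identical copies and Gm27529 has 28, so their values are uncertain. Gm23940 lies in an intron of Ppp6r3 on the opposite strand, and Gm27529 in an exon of Rpl19-ps6 on the same strand. All 7 entries are under 200 nucleotides long, where 1 read is worth many FPKM (7.78 to 15.3 at 60 nucleotides). Mir7233 rested on 5, 3 and 2 reads in HypEV, and Mir744 on 4, 4 and 5 reads in NorEV.

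The 2985 genes with an unadjusted p under 0.05, 280 of them higher and 2705 lower in HypEV, compare with 2206 that chance would give. Other splits of the 6 libraries into 2 groups of 3 gave 1138 to 2276 such genes. The exception was NorEV 1, HypEV 1 and HypEV 3 against the rest, with 7691. The groups did not overlap in 5239 genes (11.9%, where chance gives 10%). The median log2 fold change of all tested genes was -0.44, on the log2(FPKM + 1) scale, which understates the change of genes with low values. It was -0.20 without HypEV 1 and -0.73 without HypEV 2, whose own median log2 value (3.06) was close to that of NorEV 3 (3.07). With each library centred on its median no gene passed, 1127 genes were higher and 1394 lower at an unadjusted p under 0.05, and the median log2 fold change was 0.01. In 20 simulated sets no gene differed in its share of reads outside the Gm23935 family. Of these sets 12 gave at least 7 calls (0 to 24, median 8.5), and 98.4% of the calls were genes under 200 nucleotides. The sets kept FPKM scaled to all fragments, so their calls mix the spread of reads with the shift from the totals. They also gave all genes 1 common spread, which genes with few reads need not have. The count was 0 to 71 with 1 library left out, 71 of them without HypEV 2. On reads recovered from the values, limma-voom, chosen after seeing the data, called 235 genes, and 59 with the Gm23935 family left out of the totals. In simulated data limma on log2(FPKM + 1) called 29 of 50 genes changed 16-fold and 0 of 50 changed 2-fold, and limma-voom 50 of 50 and 3 of 50.

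Fewer than 5 genes passed in the higher direction, and the other 9 genes with the smallest p there are given as values that did not pass. Cox7a1, a subunit of mitochondrial cytochrome c oxidase of heart and skeletal muscle, had 16.4, 9.98 and 7.80 FPKM in HypEV and 0, 2.92 and 1.38 in NorEV (log2 fold change 2.50 ± 0.67 SE, adjusted p = 0.583). The microRNA gene Mir217 had 12.97, 32.02 and 35.05 FPKM in HypEV and 0, 6.55 and 0 in NorEV (adjusted p = 0.494). Mir7675 had 24.2, 47.7 and 13.1 FPKM in HypEV and was listed at 0 in NorEV (adjusted p = 0.0874). Mir8091 (16.8, 79.6 and 38.1 FPKM in HypEV; 0, 15.3 and 0 in NorEV) had an adjusted p of 0.598. The 5S ribosomal RNA genes n-R5s10 (94.2, 5.81 and 6.36 FPKM in HypEV, listed at 0 in NorEV) and n-R5s88 (39.6, 11.7 and 12.8 against 0, 0 and 5.67) both had adjusted p-values of 0.572, and n-R5s88 has 53 near-identical copies. The small nucleolar RNA genes Snora73b (with 2 near-identical copies; 4.56, 13.5 and 3.69 FPKM in HypEV, listed at 0 in NorEV) and Snora23 (43.1, 3.76 and 32.9 against 0, 3.85 and 0) had adjusted p-values of 0.572 and 0.604. Igkv4-54, an immunoglobulin variable gene segment with 20 near-identical copies, had 6.63, 5.90 and 6.45 FPKM in HypEV and was listed at 0 in NorEV (adjusted p = 0.427).

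All 7 tested mitochondrially encoded mRNAs, which code for subunits of the respiratory chain, were higher in HypEV. The median of the list lay 1.66 log2 units above that of all tested genes (limma camera, preset correlation 0.01, adjusted p = 2.13e-08). The adjusted p was 0.358 with an estimated correlation in camera. Leaving out the 3 libraries with most Gm23935 reads, chosen after seeing the data, leaves 2 NorEV libraries and 1 HypEV library. The spread in HypEV cannot be measured there, so only the effect is given: the list median lay 1.58 log2 units above that of all tested genes. With 1 library left out the list median lay 1.13 to 2.06 above that of all tested genes. In limma-voom, also chosen after seeing the data, the adjusted p with an estimated correlation was 0.0496, and 0.191 with the Gm23935 family left out of the totals. In fry, which tests whether the list moves one way and not whether it differs from other genes, the adjusted p was 0.538. None of the 7 passed by itself, nor when adjusted over the list alone. mt-Nd6, a subunit of complex I, had 1234, 62.7 and 132 FPKM in NorEV and 2730, 1269 and 4728 in HypEV (log2 fold change 3.54 ± 1.22 SE, adjusted p = 0.705). mt-Nd5, another subunit of complex I, had 17.1, 9.31 and 2.57 FPKM in NorEV and 17.7, 28.1 and 38.6 in HypEV (1.67 ± 0.63 SE, adjusted p = 0.720). The other tested members were mt-Nd1 (log2 fold change 1.11 ± 0.58 SE), mt-Nd2 (0.60 ± 0.64), mt-Nd4 (1.53 ± 0.71), mt-Co1 (1.08 ± 0.76) and mt-Cytb (1.22 ± 0.66). HypEV 2 and NorEV 1 had similar shares of mitochondrial reads (0.105% and 0.0973%) and more than NorEV 2 and 3 (0.0163% and 0.0118%).

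The mitochondrial values were uneven along the mitochondrial genome. mt-Nd6 is the only mitochondrial mRNA on the minus strand of the reference, and it was above the highest of the other 12 in every library, by 5.48 to 122 times. Genes on the minus strand held 79.96%, 26.5% and 67.8% of the mitochondrial reads in NorEV 1, 2 and 3 and 84.4%, 79.3% and 86.3% in HypEV 1, 2 and 3. All 14 tRNA genes of the plus strand were listed at 0 in all libraries, as were 2 of the 8 on the minus strand (mt-Tn and mt-Tc) and the mRNAs mt-Co3, mt-Nd3, mt-Nd4l and mt-Atp8. Whether reads could be placed on these genes at all was not tested, so a value of 0 does not show that their RNA was absent.

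**Figure D3:**
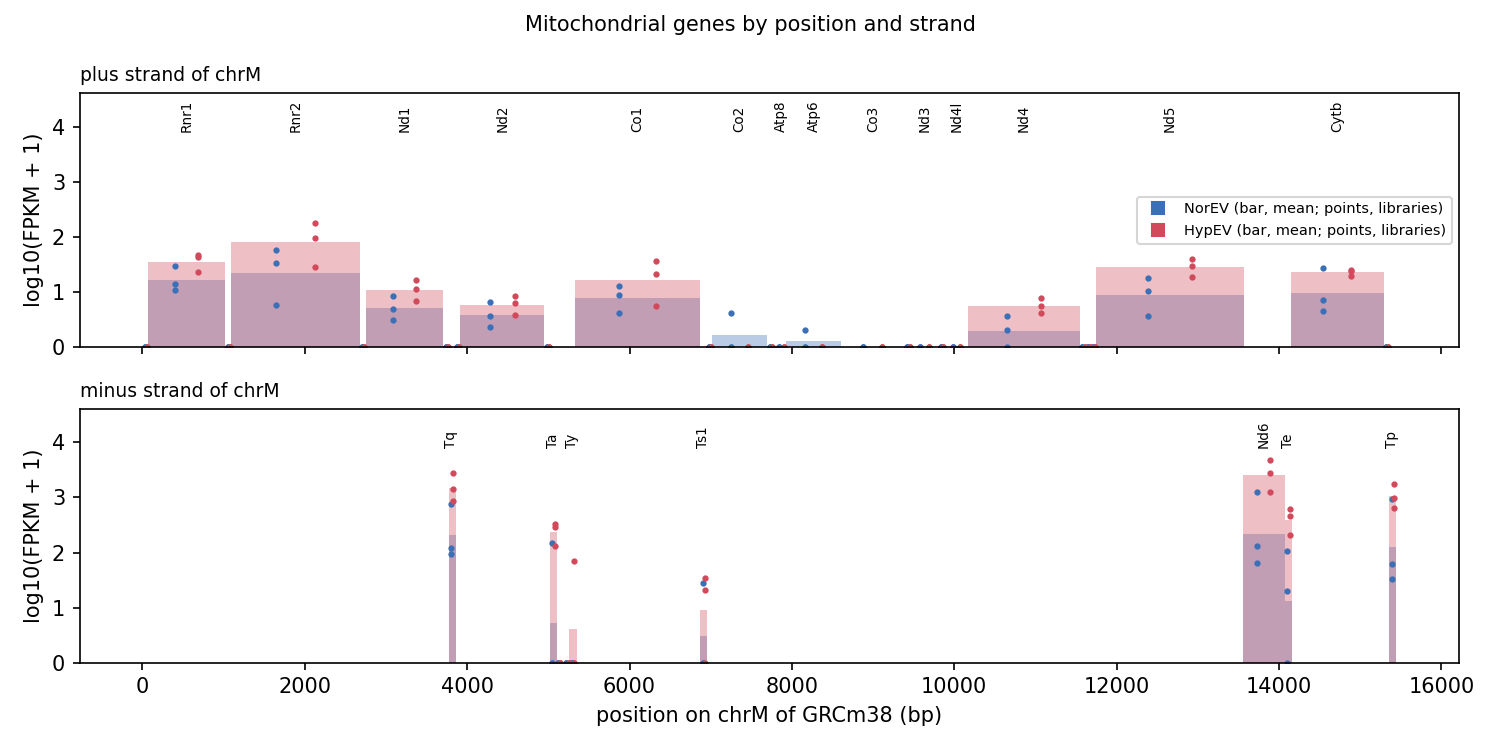
FPKM of mitochondrial genes by position on the mitochondrial genome and by strand, as log10(FPKM + 1); overlaid bars are the mean of log10(FPKM + 1) of each group (NorEV blue, HypEV red) and points the libraries. On the minus strand mt-Nd6 reached 62.7 to 1234 FPKM in NorEV and 1269 to 4728 in HypEV, and mt-Nd5 on the plus strand 2.57 to 17.1 and 17.7 to 38.6.

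Cytosolic ribosomal protein genes were also higher relative to other genes (adjusted p = 0.00841, camera), with 60 of 77 above the median of all tested genes. The adjusted p was 0.966 with an estimated correlation, 0.179 without NorEV 2 and 0.136 without HypEV 3. The list median lay 0.34 log2 units above that of all tested genes, and 0.17 (without NorEV 2) to 0.42 with 1 library left out. The median of the list was -0.11 in itself, with 33 members higher and 44 lower, so its sign differs from that of the camera result. Rpl35 had a log2 fold change of 1.37 ± 0.59 SE (3.46 ± 2.36 FPKM in NorEV and 9.33 ± 1.80 in HypEV, SD, n = 3) and Rpl39 one of -0.89 ± 0.40 SE (30.7 ± 4.55 and 16.5 ± 5.14). Neither passed (both adjusted p = 0.720).

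Of 15 abundant small non-coding RNAs, 7 were higher and 8 lower, none of which passed, and the list as a whole stood above other genes (adjusted p = 0.00841, camera). The adjusted p was 0.378 with an estimated correlation, 0.120 with each library centred on its median, 0.249 after quantile normalization and 0.0614 with the Gm23935 family left out of the totals. Its median was -0.09 and its mean 0.23, so the 2 differ in sign. Without HypEV 1 the adjusted p was 0.350 and without HypEV 3 it was 0.193. The list median lay 0.36 log2 units above that of all tested genes, 0.14 without HypEV 3, 1.21 without HypEV 2 and -0.08 without the 3 libraries with most Gm23935 reads. Scarna13, a guide RNA of Cajal bodies, had 3.33, 2.57 and 0 FPKM in NorEV and 13.6, 7.55 and 19.3 in HypEV (adjusted p = 0.605); Snora73b, the other member with the smallest p, is given with the genes that did not pass. In fry, which does not compare lists with other genes, 0 of the 33 lists passed in one direction (smallest adjusted p = 0.538) or in either direction (0.438). Apart from the mitochondrial list, list medians minus that of all tested genes lay between -0.13 (endothelial, mural and fibroblast markers) and 0.74 (replication-dependent histones). Counts of list members higher or lower in HypEV are by the values as deposited, and lists whose median lay above that of all tested genes turn higher once libraries are centred on their medians.

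**Figure D4:**
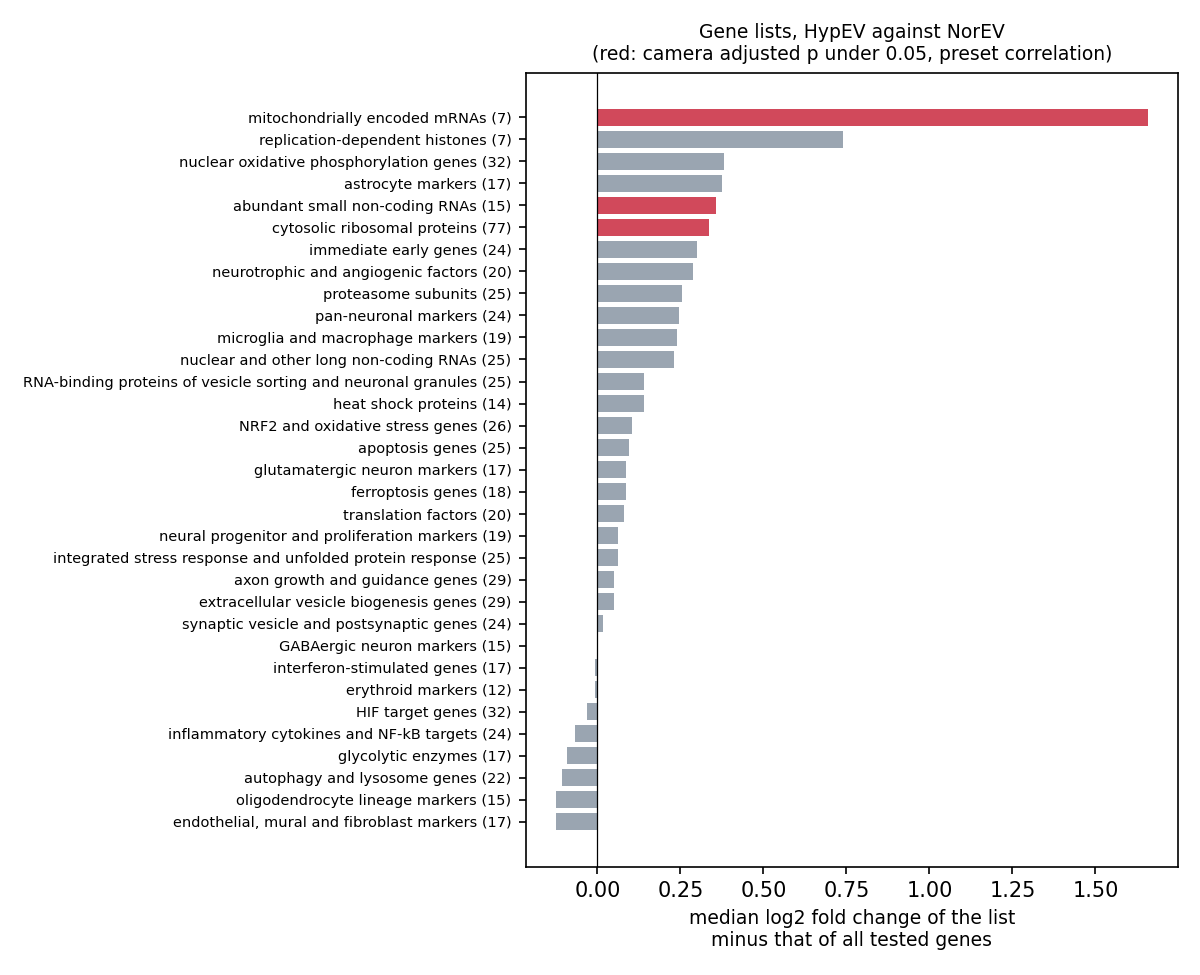
Median log2 fold change (HypEV against NorEV) of each fixed list minus the median of all tested genes; bars are lists, with the number of tested genes in brackets, and red bars passed in camera with a preset correlation. Mitochondrially encoded mRNAs lay at 1.66, abundant small non-coding RNAs at 0.36 and cytosolic ribosomal proteins at 0.34, and none of these 3 passed with an estimated correlation in this setting; with 1 library left out they lay at 1.13 to 2.06, 0.14 to 1.21 and 0.17 to 0.42.

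The targets of the hypoxia-inducible factor HIF, which many cells raise at low oxygen, did not stand apart in HypEV (adjusted p = 0.753, camera). Of 32 tested targets 2 were higher and 30 lower, none of which passed, and 13 lay above the median of all tested genes, which was itself lower. The list median lay -0.03 log2 units from it. Ldha, the lactate dehydrogenase A subunit, had 84.1 ± 36.0 FPKM in NorEV and 35.7 ± 23.9 in HypEV (SD, n = 3; log2 fold change -1.31 ± 0.56 SE, adjusted p = 0.720). Nos2, the inducible nitric oxide synthase, had 13.2 ± 2.13 and 7.19 ± 3.36 FPKM (-0.86 ± 0.47 SE, adjusted p = 0.738). Glycolytic enzymes had 3 members higher and 14 lower (adjusted p = 0.780), with Pgk1, phosphoglycerate kinase, at 10.9 ± 1.06 and 5.05 ± 2.87 FPKM (-1.07 ± 0.49 SE). None of the 17 passed.

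None of the stress and death lists passed, and no member of them did so by itself. Of 25 genes of the integrated stress and unfolded protein responses 4 were higher and 21 lower (adjusted p = 0.913, camera). Dnajb9, a chaperone of the endoplasmic reticulum, had 23.5 ± 4.99 FPKM in NorEV and 7.15 ± 3.20 in HypEV (SD, n = 3; log2 fold change -1.66 ± 0.47 SE, adjusted p = 0.604), and Pdia6, a protein disulfide isomerase, 17.3 ± 4.98 and 9.06 ± 3.57 (-0.89 ± 0.46 SE). Apoptosis genes had 4 members higher and 21 lower (adjusted p = 0.933). The anti-apoptotic gene Mcl1 had 42.9 ± 7.17 and 17.2 ± 5.28 FPKM (-1.30 ± 0.40 SE, adjusted p = 0.637), and Apaf1, a part of the apoptosome, had a log2 fold change of -1.12 ± 0.62 SE. Ferroptosis genes had 2 higher and 16 lower (adjusted p = 0.913), with the lipid peroxidase gene Gpx4 at -1.09 ± 0.42 SE and the transferrin receptor Tfrc at -0.92 ± 0.45 SE. Genes of NRF2 and oxidative stress had 6 higher and 20 lower (adjusted p = 0.780), with Gpx4 again and Sod1, superoxide dismutase, at -1.25 ± 0.59 SE. Heat shock proteins had 4 higher and 10 lower (adjusted p = 0.780), with Cryab at -1.12 ± 0.80 SE and Hsph1 at -0.48 ± 0.38 SE. Autophagy and lysosome genes had 3 higher and 19 lower (adjusted p = 0.780), with Atg12 at -1.11 ± 0.51 SE and Wipi1 at -0.90 ± 0.43 SE.

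Signalling and inflammatory lists did not pass in the test fixed beforehand either. Of 24 immediate early genes, which neurons induce with activity, 10 were higher and 14 lower (adjusted p = 0.236, camera; without NorEV 3 0.0334, and 0.955 there with an estimated correlation), with Npas4 at -0.80 ± 0.51 SE and Jund at 1.12 ± 0.85 SE on the log2 scale. Inflammatory cytokines and NF-kB targets had 6 higher and 18 lower (adjusted p = 0.780), with Il6 at -1.25 ± 0.48 SE and Il18 at -1.90 ± 0.85 SE. Interferon-stimulated genes had 3 higher and 14 lower (adjusted p = 0.913), with Ifit2 at -0.97 ± 0.42 SE and Ifi27 at -0.65 ± 0.40 SE. Neurotrophic and angiogenic factors had 6 higher and 14 lower (adjusted p = 0.663), with Hgf at -0.88 ± 0.53 SE and Gdf15 at -1.39 ± 0.91 SE.

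Markers of neurons and of the other cells a cortical culture could hold were mostly lower in HypEV, as was the median tested gene, and none of their lists passed in the test fixed beforehand. Pan-neuronal markers had 7 members higher and 17 lower (adjusted p = 0.780, camera), but lay 0.25 log2 units above the median of all tested genes, so that their direction flips once libraries are centred on it. Uchl1, a deubiquitinase abundant in neurons, had 27.5 ± 11.6 FPKM in NorEV and 11.4 ± 4.32 in HypEV (SD, n = 3; log2 fold change -1.17 ± 0.49 SE), and Eno2, neuronal enolase, 12.7 ± 2.96 and 7.29 ± 3.28 (-0.80 ± 0.49 SE). Glutamatergic markers had 5 higher and 12 lower (adjusted p = 0.913), with Neurod1 at -1.39 ± 0.57 SE and Slc17a6 at -0.83 ± 0.51 SE. GABAergic markers had 3 higher and 12 lower (adjusted p = 0.913), with Npy at -1.76 ± 0.91 SE and Sst at -1.60 ± 0.99 SE. Synaptic vesicle and postsynaptic genes had 3 higher and 21 lower (adjusted p = 0.780). Axon growth and guidance genes had 2 higher and 27 lower (adjusted p = 0.780), with Dpysl2 at -1.03 ± 0.40 SE and Dpysl3 at -0.82 ± 0.45 SE.

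Astrocyte markers had 7 members higher and 10 lower (adjusted p = 0.244, camera), but 14 of 17 lay above the median of all tested genes. The list passed as higher with the Gm23935 family left out of the totals, chosen after seeing the data, in FPKM (adjusted p = 0.0378, camera) and in limma-voom (0.00886). With an estimated correlation it did not pass in either (adjusted p = 0.516 and 0.405), nor in the values as deposited (0.966). Among its members were the glutamate transporter Slc1a3 at -0.97 ± 0.58 SE and S100b at -0.82 ± 0.60 SE. Microglia and macrophage markers had 7 higher and 12 lower (adjusted p = 0.780), with C1qc at -1.48 ± 0.55 SE and Ptprc at -0.79 ± 0.38 SE. Oligodendrocyte lineage markers had 5 higher and 10 lower (adjusted p = 0.914), with Olig2 at -1.40 ± 0.70 SE and Mag at -1.10 ± 0.56 SE. Markers of endothelial, mural and fibroblast cells had 2 higher and 15 lower (adjusted p = 0.495). Acta2, smooth muscle actin, had 43.7 ± 7.76 FPKM in NorEV and 14.1 ± 11.05 in HypEV (SD, n = 3; -1.79 ± 0.53 SE, adjusted p = 0.622), and Kdr, a VEGF receptor, had a log2 fold change of -1.47 ± 0.53 SE. Neural progenitor and proliferation markers had 6 higher and 13 lower (adjusted p = 0.780), with Cdk1 at -1.30 ± 0.56 SE and Top2a at -0.83 ± 0.44 SE. Erythroid markers had 3 higher and 9 lower (adjusted p = 0.780), with Alas2, an enzyme of heme synthesis, at -1.55 ± 0.73 SE.

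Genes of vesicle biogenesis did not stand apart in HypEV, with 3 members higher and 26 lower (adjusted p = 0.780, camera). Cd82, a tetraspanin, had 35.7 ± 1.56 FPKM in NorEV and 15.8 ± 0.737 in HypEV (SD, n = 3; log2 fold change -1.13 ± 0.35 SE, adjusted p = 0.637). Chmp2a, of the ESCRT-III complex that pinches off vesicles, had 56.4 ± 25.7 and 19.2 ± 5.61 FPKM (-1.46 ± 0.45 SE, adjusted p = 0.637). RNA-binding proteins of vesicle sorting and neuronal granules had 9 higher and 16 lower (adjusted p = 0.753). They passed as higher only in limma-voom with the Gm23935 family left out (adjusted p = 0.0365, camera), and not there with an estimated correlation (0.561). Among them Fxr1 had 79.6 ± 50.1 and 24.9 ± 4.92 FPKM (-1.48 ± 0.49 SE) and Fxr2 24.1 ± 4.06 and 11.9 ± 1.56 (-0.96 ± 0.38 SE). Both are relatives of the fragile X protein.

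The remaining lists did not pass in the test fixed beforehand. Nuclear oxidative phosphorylation genes, which code for the respiratory subunits that mitochondria import, had 14 higher and 18 lower (adjusted p = 0.236, camera), with Cox6a1 at -1.68 ± 0.52 SE and Ndufa4 at -1.13 ± 0.46 SE. Translation factors had 8 higher and 12 lower (adjusted p = 0.780), with Eif3h at -1.02 ± 0.39 SE and Eif4e at -1.04 ± 0.56 SE. Proteasome subunits had 9 higher and 16 lower (adjusted p = 0.241), with Psmb2 at 1.49 ± 0.80 SE and Psmb7 at -0.85 ± 0.48 SE. Nuclear and other long non-coding RNAs had 9 higher and 16 lower (adjusted p = 0.236), with the small nucleolar RNA hosts Snhg11 at -1.30 ± 0.44 SE and Snhg12 at 1.53 ± 0.73 SE. With the Gm23935 family left out of the totals, nuclear oxidative phosphorylation genes (adjusted p = 0.0386, camera) and long non-coding RNAs (0.0417) passed as higher, and the latter also in 4 other settings (0.00113 to 0.0277), array weights among them. With an estimated correlation neither passed in these settings (adjusted p = 0.452 to 0.987). Replication-dependent histones had 5 higher and 2 lower (adjusted p = 0.236), with Hist1h1e at 0.39 ± 0.60 SE and Hist1h1c at -0.37 ± 0.66 SE.

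The libraries of the 2 groups overlapped in how many genes they held. NorEV libraries had 41017 ± 3241 genes above 0 and HypEV libraries 37509 ± 3331 (SD, n = 3; difference -3508, exact permutation test, two-sided, p = 0.2). The 50 most abundant genes held 33.4% ± 26.9 of the summed FPKM in NorEV and 78.5% ± 28.8 in HypEV (p = 0.2, exact). With the Gm23935 family left out, the difference of 45.1 percentage points became 9.66. Genes of the mitochondrial genome held 0.123% ± 0.121 and 0.243% ± 0.190 of the summed FPKM (p = 0.5, exact), and 0.255% ± 0.337 and 1.68% ± 0.880 with that family left out of the sum (p = 0.1, exact). Of the recovered reads they held 0.0418% ± 0.0481 and 0.208% ± 0.114 (p = 0.1, exact, the smallest possible). Correlations of log2 values between libraries (Pearson, across genes, which are not independent replicates) were 0.484 to 0.647, and the pair of highest correlation was NorEV 2 and NorEV 3.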

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

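The settings with limma-voom, without the Gm23935 family, with a minimum length, without 3 libraries, by recovered reads, with thinned reads or with an estimated correlation beside another change were chosen only after the results were seen. Of the alternatives, quantile normalization (5 genes), a mean of at least 5 FPKM (7) and totals without the Gm23935 family (7, of which 6 were among the first 7) left the count of genes within 1.5 times, with 2 higher and 3 lower genes under quantile normalization and 2 higher without the family. The count was 0, with 0 higher and 0 lower, under median scaling (2521 genes at an unadjusted p under 0.05), no filter (3149), no trend (2821), a pseudocount of 0.1 (2649), a minimum of 200 nucleotides (2948) and without the 3 libraries with most Gm23935 reads (3783), which leaves 1 HypEV library that is assumed to vary like the 2 of NorEV. It was 75 (10 higher, 65 lower) with array weights, 235 (16 and 219) with limma-voom, 59 (19 and 40) with limma-voom without the family and 2925 (278 and 2647) at an unadjusted p under 0.05 with a log2 fold change above 1, a looser threshold by construction. Beside the split of 280 higher and 2705 lower genes at an unadjusted p under 0.05, median scaling gave 1127 and 1394, quantile normalization 1234 and 1441 and totals without the family 852 and 1639. Leaving out 1 library gave 0 to 71 genes, 0 to 4 higher and 0 to 67 lower: 71 without HypEV 2, 2 without NorEV 1 or HypEV 1, and 0 without NorEV 2, NorEV 3 or HypEV 3. The first 7 were all among the 71 without HypEV 2. None of them was among the 2 without NorEV 1 (Mir187 and mt-Ta) or the 2 without HypEV 1 (Traj16 and Trbd1). With the replicate number as a block 0 genes passed (0 higher, 0 lower; 3351 at an unadjusted p under 0.05) and 3 lists did. Deviations of libraries with the same number correlated at 0.0446, 0.102 and -0.0582. HypEV 1, HypEV 2 and NorEV 2 correlated best with the library of their own number, and HypEV 3, NorEV 1 and NorEV 3 did not. These weak values do not show that the numbers pair the libraries, and they cannot exclude it. The count of lists, 3, became 0 with an estimated correlation and without the 3 libraries, 6 with limma-voom without the family, 5 in FPKM without the family, and 1 to 4 with 1 library left out (1 without HypEV 3). It was 2 to 4 in the other settings. Lists that gained a call were astrocyte markers (both settings without the family), nuclear oxidative phosphorylation genes (FPKM without the family), RNA-binding proteins (limma-voom without the family), long non-coding RNAs (both of these, limma-voom, array weights and without NorEV 1) and immediate early genes (without NorEV 3). With an estimated correlation 0 of these 10 further calls remained (adjusted p = 0.405 to 0.987), while the mitochondrial list passed in limma-voom (0.0496). The mitochondrial list passed in 19 of 21 settings, the ribosomal list in 17 and the small non-coding list in 14, and all but 1 of these settings used the preset correlation. With an estimated correlation (camera) the mitochondrial list had adjusted p-values of 0.358 at first, 0.324 with array weights, 0.418 without NorEV 1 and 0.705 without NorEV 3. Without the family they were 0.191 in limma-voom and 0.516 in FPKM. The ribosomal and small non-coding lists passed in none of the settings with an estimated correlation. Of 1669 values of single genes under the alternatives 1526 kept their direction and side of the threshold, 94 were no longer past it, 43 came past it and 6 changed sign unpassed. They are values of 86 genes, at most 7 of which had passed at first. Most of the 1526 are thus genes that failed and kept failing, and all of the 94 are losses among the genes that had passed. None that had passed changed sign. The difference in detected genes stayed negative (-5365 to -2132 with 1 library left out), and those in the mitochondrial share (0.0209 to 0.210) and the share of the 50 most abundant genes (35.7 to 61.7) stayed positive. Except where said, the cause was not tested. In simulated data limma on log2(FPKM + 1) called 6 of 50 genes changed 8-fold, and limma-voom on the reads 46 of 50 (18 of 50 at 4-fold).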

Other observations

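The tests with limma-voom, of sources of the reads, of the share of Gm23935, of thinned reads and of the mitochondrial genes were chosen only after the results were seen. The counts over other splits of the libraries were not. On the recovered reads outside the Gm23935 family, limma-voom called 59 of 42339 genes, 19 higher and 40 lower in HypEV, of which 27 were annotated as protein-coding (9 higher, 18 lower). The 9 higher were mt-Nd6, mt-Nd5, Lars2, Nmi, Zfp90 and the predicted genes Gm10801, Gm10722, Gm21738 and Gm11168. The groups did not overlap in 43 of the 59, and none was among the 7 genes past the threshold in FPKM. In simulated data limma-voom called 15 of 41744 unchanged genes. That run kept the family in the totals and gave all genes 1 common spread, so it sets no false-call rate for the 59. All genes named here were chosen after their values were seen. The mitochondrial genes mt-Nd6, mt-Nd5, mt-Tq and mt-Tp were higher. mt-Nd6 had 257 ± 358 RPM (reads scaled to the library's reads outside the family) in NorEV and 2243 ± 1379 in HypEV (SD, n = 3; log2 fold change 4.02 ± 0.53 SE, adjusted p = 1.5e-05). Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, lies on chromosome 9 and had 531 ± 371 and 1494 ± 904 RPM (1.61 ± 0.27 SE, adjusted p = 0.000575). Its value is a total over the gene, and where its reads fell was not seen. A change of its messenger RNA is therefore not shown. Rnu11, a small nuclear RNA of the minor spliceosome, had 142 ± 151 and 328 ± 47.4 (1.87 ± 0.32 SE, adjusted p = 0.000874). Nmi, an interferon-induced gene, had 92.3 ± 58.7 and 273 ± 151 (1.54 ± 0.34 SE, adjusted p = 0.0267). Gm10801, Gm10722, Gm21738 and Gm11168, predicted genes with 4 to 11 near-identical copies each, were higher by 2.03 to 2.31 log2 units. The split of reads between such copies is uncertain, so these 4 are not separate changes of coding genes. Of the higher genes named here, the groups overlapped for mt-Tp, Lars2, Rnu11, Nmi, Gm10801, Gm10722 and Gm21738.

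The lower genes in the same test included Usp30, a deubiquitinase of the outer mitochondrial membrane, with 284 ± 69.4 RPM in NorEV and 107 ± 40.7 in HypEV (SD, n = 3; log2 fold change -1.41 ± 0.27 SE, limma adjusted p = 0.00561). Chchd3, a protein of mitochondrial cristae, had 246 ± 121 and 91.7 ± 15.5 (-1.35 ± 0.30 SE, adjusted p = 0.0257). Cenpj, a centriole protein, had 735 ± 422 and 268 ± 8.85 (-1.35 ± 0.23 SE, adjusted p = 0.00106), and Ehmt1, a histone methyltransferase, 442 ± 89.1 and 228 ± 29.1 (-0.94 ± 0.21 SE, adjusted p = 0.0257). The odorant receptor gene Olfr1256 (369 ± 206 and 97.1 ± 32.5; -1.87 ± 0.30 SE) and the serpin gene Serpina1f (365 ± 130 and 123 ± 8.35; -1.53 ± 0.26 SE) were lower as well. In these 6 genes all HypEV libraries were below all NorEV libraries.

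Neuronal and non-neural genes had similar levels, with a ratio of their median FPKM of at most 1.91 in any library, but levels were not even: glycolytic enzymes lay at the 89.0th percentile of protein-coding genes and olfactory receptor genes at the 14.6th. Reads spread evenly over the genome, such as genomic DNA, could be a part of them: olfactory receptor genes, which most tissues do not transcribe, held at most 0.453 times the reads per kilobase of exons of all protein-coding genes, less than an even spread would give. This leaves the explanation open, since the ratio stayed above the 0.1 set as its bound and reads shared between near copies may lower it. A neuronal messenger RNA source stays open, since ribosomal protein and translation factor genes lay at the 79.1st percentile of protein-coding genes, above the middle but below the 90th. Counting on the strand opposite to the RNA could give both the flat levels and the high mt-Nd6. It would raise genes that lie within opposite-strand exons, but 273 such genes had 0.747 times the median FPKM of genes without overlap, while mt-Nd6 was over 10 times the highest other mitochondrial mRNA in 5 of 6 libraries, so it stays open. No biological explanation was tested.

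Most genes were lower in HypEV. With the reads of Gm23935 and its near-identical copies left out of the totals, the median log2 difference went from -0.44 to -0.12, which suggests that these reads account for most of the shift in FPKM. Fewer reads left for other genes stay open as a cause of the lower number of detected genes: with reads outside the family thinned to 1007201 per library, the difference was -2949, against -3508 before, and the groups overlapped in both (exact permutation p = 0.2 each). A difference in the vesicles' RNA between hypoxic and normoxic neurons stays open and untested.

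Mitochondrial values were higher in HypEV. They may follow the make-up of the libraries: over the 6 libraries, the share of mitochondrial reads and that of Gm23935 reads had a Spearman's rho of 0.886 (exact permutation p = 0.0333) and a Pearson's r of 0.666 (exact permutation p = 0.131), or 0.820 without HypEV 1 and HypEV 3, the 2 libraries farthest from the median. With mitochondrial reads as a share of those outside the family, rho was the same and r was 0.857 (exact permutation p = 0.0375), or 0.831 without these 2. Adjusted over the 2 relations, the last p was 0.075 and the others were unchanged, and 3 libraries per group are too few for a value within groups. Mitochondrial DNA as the source of the mt-Nd6 values is argued against. mt-Nd6 was at least 22.1 times the median of the other 12 mitochondrial mRNAs in each library, with that median taken as at least 1 FPKM. Of these 12, mt-Co3, mt-Nd3, mt-Nd4l and mt-Atp8 were at 0 in all libraries, for reasons not tested, which lowers the median. Against the highest of the 12, mt-Nd6 was 5.48 times (NorEV 2) to 122 times (HypEV 3) as high, and DNA would give both strands alike. For the other tested members of the list, all on the plus strand and at no more than 38.6 FPKM, these ratios cannot tell, and DNA stays open. An effect of the OGD/R treatment on the mitochondrial RNA in vesicles stays open and untested.

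The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. As many genes passed in 2 of the 10 splits, the real one (7 genes) included, and the highest other split gave 245. As many lists passed in 2 of 10, with 3 lists in the real split and 3 in the highest other. The split with 245 genes set NorEV 1, HypEV 1 and HypEV 3 against the rest, and these are the 3 libraries with most Gm23935 reads. It points to a structure of the samples that crosses the groups.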
